A study of Mus musculus with 2 samples.

How the data were processed

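Per the labels, stranded paired-end libraries were made from polyadenylated RNA over 200 nucleotides, depleted of ribosomal RNA, from urinary bladder of C57BL/6J mice of both sexes at 8 weeks of age, with spike-in RNA added. The 2 libraries carry separate biosample labels and are numbered as biological replicates, but both name the same donor entry. The labels speak of littermates but do not say how many animals each library holds or whether the animals differ between libraries. The SD therefore measures only the spread between these samples, which may be partly technical. The p-values cover counting error only.

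The authors deposited, for each library, gene and transcript tables on mm10 with GENCODE annotation M4, per the descriptions deposited with the samples. Per the file headers these tables give expected counts, estimated fragments that need not be whole numbers, and TPM as a maximum likelihood value and a posterior mean. TPM was scaled over all rows of each file, spike-ins included. The aligner, the counting tool and their versions are not given in the sources used here. For the whole series the authors deposited mm9 tables of Ensembl genes (release 65) and of assembled models with 2 RPKM values and a reproducibility value (IDR) each, exon coordinates, and splice junctions with read counts summed over both libraries. The RPKM values are not tied to a replicate by any label, so only their mean was used. Each Ensembl gene was listed more than once with equal RPKM (74620 lines, 37310 genes) and was taken once. A contig table and the mm9 transcript tables were not used here.

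Each mm10 table had 69691 rows, of which 43346 were Ensembl genes, 96 were spike-ins and 26248 carried numbers in place of gene names and held 0 and 5.99 counts. Rows that are not Ensembl genes took 5.01% of the expected counts in replicate 1 and 5.98% in replicate 2 and were left out of library sizes and tests. Of the Ensembl genes, 42462 matched GENCODE M21 by identifier without version and took symbols and mm10 positions from it. Of 264 list entries 1, Muc16, matched no row. Transcript names and protein lengths come from M21, whose transcript versions often differ from those quantified.

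Total expected counts were 104610979 and 111741334, of which 99367453 and 105057347 lay on genes. Shares of a list are the sum of its TPM as a percent of all gene TPM. Ratios between libraries use log2 with a pseudocount of 0.5 TPM, which understates ratios of low genes, and list medians are given relative to the median of genes with a mean of at least 1 TPM (0.08). The percentile of a list comes from 10000 random lists, each member being replaced by 1 of the 200 genes nearest in mean expression. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, with TMM normalization and its expression filter. The biological coefficient of variation is the square root of the common dispersion in a design with an intercept alone. The two-sided exact binomial test per gene compared the libraries with Benjamini-Hochberg adjustment at 0.05 and a fold of at least 2. Correlations use log2(TPM + 1). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

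On simulated data with 18003 genes for this comparison, a coefficient of variation of 0.2 was recovered as 0.200. The binomial rule was tried on separate simulated counts with counting error only. It recovered 36% of genes changed 2-fold, 96% of those changed 3-fold, 100% of those changed 4-fold and 100% of those changed 8-fold. There 3 unchanged genes were called, a count that does not carry over to libraries that differ beyond counting error. For lists of 10 genes drawn from 14533, 3.5% of unshifted lists and 97.5% of lists shifted by 0.5 fell outside the central 95%. The GC and length correction, run on 13473 genes with a simulated GC trend, returned a shift of 1 as 1.09 and a shift of 0 as 0.04. A trend with length was not simulated.

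The 30 gene lists, the gene pairs, the splice form genes, the tests and the alternative settings were fixed before the data were examined. The genes named are list members (for each list at least the 3 of highest mean and those under 1 TPM in both libraries), the 20 genes of highest mean outside the mitochondrial list, the 10 largest ratios in each direction among genes of at least 5 TPM and 200 counts, and transcripts with a mean share of at least 10%. Some genes and gene pairs that this rule covers are not reported here, but the counts, shares and medians of their lists include them. Alternatives were other detection levels, the posterior mean TPM, other pseudocounts and filters, CPM of the expected counts, DESeq2 1.42.0 size factors, leaving out each library, the mm9 values and removing mitochondrial genes. A correction for GC content and length was added after the data were seen, as a cubic trend removed from 13447 genes and fitted without both adipocyte lists, the smooth muscle and superficial urothelium lists, Gm42418, mt-Rnr1, mt-Rnr2 and Lars2. Under an alternative, a share or median was taken as kept where it moved by less than its SD, a correlation or dispersion where it was equal to 2 decimals, and a count where it stayed within 1.5 times. Leaving out 1 of 2 libraries always moves their mean by less than their SD. Shares and pair ratios were therefore kept there by construction, and only their range is informative.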

Results

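The series profiles the polyadenylated RNA of 1 tissue, the urinary bladder of adult C57BL/6J mice at 8 weeks of age, which the labels describe as littermates of both sexes. It holds 1 group, adult bladder, with 2 libraries labelled as biological replicates 1 and 2. The bladder wall consists of a stratified epithelium (the urothelium), a connective tissue layer and a thick smooth muscle layer (the detrusor). Estimated fragment counts on annotated genes came to 99367453 in replicate 1 and 105057347 in replicate 2. A count of 0 at this depth allows up to 0.0302 and 0.0286 CPM (counts scaled to the gene total), a floor that stands for 3 counts and covers counting error only. With no second group there is no contrast between conditions, so levels are given as the mean ± SD of the 2 libraries in TPM, a length-adjusted transcript abundance scaled to the library total, with n = 2 throughout, and gene positions are on the mm10 assembly. A test between the libraries compares those libraries only.

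Outside the mitochondrial genome, Sprr2a2, a small proline-rich protein of cornifying and barrier epithelia (ENSMUSG00000068893.5, chromosome 3, 92215920 to 92256724), had the highest mean, 14996 ± 6459 TPM. It belongs to a cluster of near-identical copies, so its level is uncertain. Smooth muscle actin Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590) followed among protein-coding genes at 8674 ± 235 TPM, ahead of the myosin light chain Myl6 (7339 ± 474 TPM), the glutathione S-transferase Gstm1 (7331 ± 110 TPM), the actin-binding protein Tagln (6417 ± 30 TPM) and the elongation factor Eef1a1 (6308 ± 971 TPM). Actg2, Rplp1, Actb, Tpm1, Rps12, Flna, Myl9, S100a6, Mgp and Tmsb4x were also among the 20 highest genes outside the mitochondrial genome, which together held 12.7% of TPM. The remaining places went to Gm42418, at 11508 TPM in replicate 1 and 826 TPM in replicate 2, and to Gm29216, Gm28437 and Gm10925, pseudogenes on chromosome 1 that are copies of mitochondrial sequence and can share its reads. In all, 14191 genes reached 1 TPM in both libraries, of which 12999 were annotated as protein coding.

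Contractile genes of smooth muscle held the largest share of TPM among the cell type lists, 3.83% ± 0.37. All 15 members were detected in both libraries, led by Acta2, Tagln (6417 ± 30 TPM) and Actg2 (6131 ± 271 TPM), with Myl9 at 3900 ± 1089 TPM, Tpm2 at 3298 ± 616 TPM, the smooth muscle myosin heavy chain Myh11 at 1642 ± 666 TPM and Myocd, a transcriptional coactivator of this programme, at 27.5 ± 9.3 TPM. The share of smooth muscle exceeded that of superficial urothelium in each library, 4.09% against 0.660% in replicate 1 and 3.56% against 0.925% in replicate 2. With n = 2, no exact test between lists can reach 0.05.

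Markers of the superficial urothelium, the umbrella cell layer that carries uroplakin plaques, held 0.793% ± 0.188 of TPM, and all 11 were detected. Upk1a had 1977 ± 516 TPM (ENSMUSG00000006313.4, chromosome 7, 30603092 to 30612847), Psca 983 ± 264 TPM, Upk3a 939 ± 251 TPM and Upk2 867 ± 205 TPM. The basal urothelium list held 0.183% ± 0.014, led by Krt7 (526 ± 45 TPM), Krt15 (471 ± 3.9 TPM) and Krt5 (364 ± 2.1 TPM). Krt14, a keratin of basal cells in many stratified epithelia, stood at 0.65 and 1.25 TPM. Whole tissue cannot show whether a list member such as Krt7 is confined to basal cells. The uroplakin pairs kept their order in both libraries: Upk2 was below Upk1a by a log2 ratio of -1.19 ± 0.04, and Upk3a was above Upk1b by 0.24 ± 0.08. Krt5 exceeded Krt20, a keratin of umbrella cells, by 3.17 ± 0.34.

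Among the 10 urothelial transcription factors, 9 were detected in both libraries. Pparg stood at 62.4 ± 10.3 TPM, Grhl3 at 51.8 ± 10.5 TPM and Gata3 at 50.3 ± 6.9 TPM, and Tfap2a at 0.49 ± 0.04 TPM was the member under 1 TPM. The list held 0.041% ± 0.001 of TPM. Barrier and transport genes held 0.098% ± 0.018, led by the water and glycerol channel Aqp3 (404 ± 63 TPM), the tight junction gene Cldn4 (252 ± 64 TPM) and Cldn8 (57.2 ± 19.8 TPM). Cldn3 (0.11 ± 0.01 TPM), Muc1 (0.78 ± 0.17 TPM) and the urea transporter Slc14a2 (0.02 and 0.03 TPM, from 4 and 3 counts) lay under 1 TPM, against 44.5 ± 5.3 TPM for Slc14a1.

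P2rx1 (ENSMUSG00000020787.10, chromosome 11, 72999103 to 73015200), an ATP-gated channel of smooth muscle, was the most abundant of the 16 neurotransmitter receptors examined, at 431 ± 32 TPM, and exceeded P2rx4 (32.7 ± 1.2 TPM) by a log2 ratio of 3.72 ± 0.16. Among muscarinic receptors Chrm3 (12.9 and 19.1 TPM) was above Chrm2 (5.73 and 4.08 TPM) in both libraries, with a log2 ratio of Chrm2 to Chrm3 of -1.17 in replicate 1 and -2.23 in replicate 2. Chrm1 (0.05 and 0.03 TPM), Chrm4 (0.04 and 0.09 TPM) and Chrm5 (0 and 1 counts) lay under 1 TPM. The beta-3 adrenergic receptor Adrb3 (11.5 ± 2.4 TPM) exceeded Adrb1 (0.82 ± 0.09 TPM) by 3.79 ± 0.15 on the log2 scale. Adra1a (0.12 ± 0.01 TPM), Adra1d (0.76 ± 0.11 TPM) and P2rx3 (0.55 ± 0.16 TPM), a channel of sensory nerve endings, were also under 1 TPM, and the log2 ratio of Adra1a to Adra1d was -2.72 ± 0.30. The 16 genes held 0.056% ± 0.002 of TPM.

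**Figure D1:**
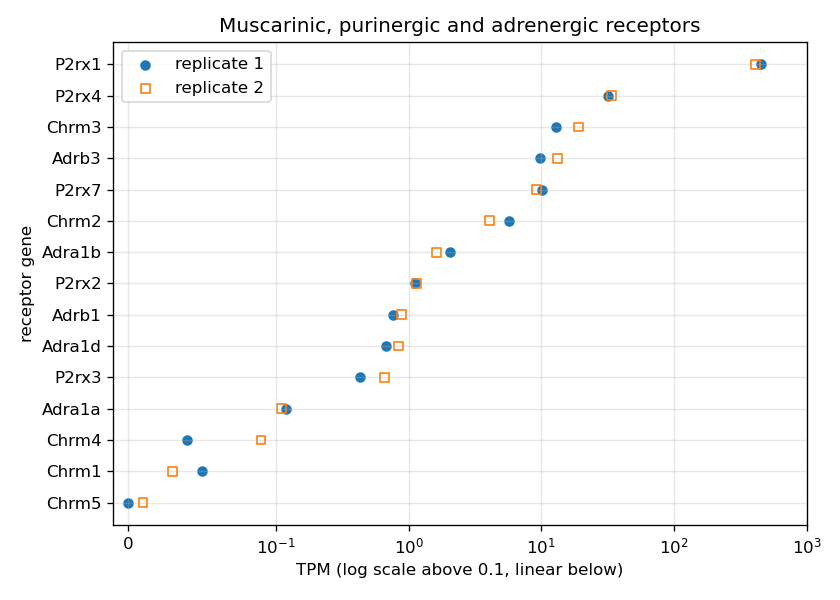
Levels of muscarinic, purinergic and adrenergic receptor genes in TPM (horizontal axis, logarithmic above 0.1 and linear below) in replicate 1 (filled circles) and replicate 2 (open squares). P2rx1 stands at 454 and 408 TPM, above all the others, and Chrm3 lies above Chrm2 in both libraries.

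Of the 13 ion and mechanosensitive channels, 10 were detected, and the list held 0.029% ± 0.001 of TPM. Piezo1, a stretch-activated channel, had 47.8 ± 3.1 TPM and exceeded Piezo2 (3.03 ± 0.16 TPM) by a log2 ratio of 3.98 ± 0.02. Trpv4 (45.5 ± 6.2 TPM) and Trpv2 (41.4 ± 2.7 TPM) differed by 0.13 ± 0.29, less than the spread between the libraries. Trpv1 (0.28 ± 0.01 TPM), Trpa1 (0.05 and 0.02 TPM) and Trpm8 (0 counts in both libraries) lay under 1 TPM. The calcium-activated potassium channel subunits Kcnma1 and Kcnmb1 had 19.6 ± 3.9 and 28.4 ± 2.7 TPM, a log2 ratio of -0.54 ± 0.15. In the mm9 RPKM values this ratio was -0.92, so its size depends on the quantification. The L-type calcium channel gene Cacna1c stood at 18.7 TPM in replicate 1 and 8.46 TPM in replicate 2. Steroid and nuclear receptors held 0.012% ± 0.0004, led by Rarg (53.9 ± 0.5 TPM), Nr3c1 (28.5 ± 1.0 TPM) and Rarb (8.86 ± 0.88 TPM). The estrogen receptor gene Esr1 stood at 3.09 ± 0.47 TPM, and Esr2 (0.37 ± 0.06 TPM) and Pgr (0.21 ± 0.04 TPM) were under 1 TPM.

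Fibroblast and matrix genes held 0.745% ± 0.024 of TPM, led by Dcn (2525 ± 218 TPM), Col3a1 (1318 ± 111 TPM) and Col1a1 (894 ± 251 TPM). The log2 ratio of Col1a1 to Col3a1 was -0.59 ± 0.29 in TPM and turned to 0.49 in the mm9 RPKM values, so its direction depends on the quantification. Endothelial genes (0.039% ± 0.002) were led by Egfl7 (132 ± 34 TPM), Pecam1 (41.1 ± 7.4 TPM) and Esam (41.1 ± 2.7 TPM), and pericyte genes (0.018% ± 0.001) by Rgs5 (101 ± 2.6 TPM), Abcc9 (18.9 ± 6.0 TPM) and Kcnj8 (18.5 ± 0.6 TPM). Glial and neuronal genes held 0.056% ± 0.018, most of it Uchl1 (432 ± 151 TPM), with the myelin gene Mbp (25.5 ± 0.5 TPM) next.

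Macrophage genes held 0.079% ± 0.006 of TPM, the largest share among the macrophage, mast cell, B cell, T cell and neutrophil lists, with Lyz2 at 331 ± 16 TPM and the complement genes C1qb at 122 ± 14 and C1qa at 98.0 ± 10.8 TPM. Mast cell genes held 0.0034% ± 0.0003 (Kit 9.18 ± 1.03, Cma1 6.70 ± 0.30 and Mcpt4 5.98 ± 0.88 TPM, Ms4a2 0.15 ± 0.02 TPM). B cell genes held 0.0027% ± 0.0001, mainly Ighm (21.7 ± 0.03 TPM), with Jchain at 1.19 ± 0.11 and Cd79b at 1.09 ± 0.26 TPM and with Cd79a (0.51 ± 0.02) and Ms4a1 (0.13 ± 0.08) among those under 1 TPM. T cell genes held 0.00084% ± 0.00005, with Lck at 2.41 ± 0.52, Cd2 at 1.63 ± 0.23 and Cd4 at 1.22 ± 0.35 TPM, and with Cd3d (0.56 ± 0.04), Cd3e (0.50 ± 0.09) and Cd8a (0.30 ± 0.19) under 1 TPM. None of the 6 neutrophil genes reached 1 TPM in either library: S100a8 had 0.73 ± 0.30, Mpo 0.57 ± 0.35, S100a9 0.31 ± 0.27, Elane 0.09 ± 0.08 and Cxcr2 0.02 TPM, and Ly6g had 0 counts. Antigen presentation and interferon genes held 0.110% ± 0.0002 (Cd74 412 ± 25, H2-Aa 206 ± 6.3 and H2-Ab1 184 ± 0.5 TPM). Mucosal defence genes held 0.0034% ± 0.0005 (Defb1 14.7 ± 3.7, Tlr4 4.88 ± 0.21 and Pigr 3.84 ± 0.02 TPM), and the cathelicidin gene Camp had 0 and 2 counts. Immediate early and stress genes held 0.040% ± 0.003, led by Junb (78.3 ± 15.9 TPM), Hspa1b (78.2 ± 4.1 TPM), which shares reads with Hspa1a, and Dusp1 (51.8 ± 6.5 TPM). Proliferation genes held 0.0028% ± 0.0004 (Cdk1 8.42 and 13.5 TPM, Top2a 3.88 ± 0.48, Ccna2 3.67 ± 0.24 and Bub1 0.58 ± 0.01 TPM).

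Markers of tissues that border the bladder differed widely in level. The adipocyte list held 0.141% of TPM in replicate 1 and 0.267% in replicate 2, led by Fabp4 (840 ± 358 TPM), Cfd (495 ± 258 TPM) and Car3 (420 ± 123 TPM). Mesothelial genes held 0.00114% in replicate 1 and 0.00253% in replicate 2, with Msln at 6.24 and 15.3 TPM, Wt1 at 3.46 ± 1.46 and Lrrn4 at 2.84 ± 1.05 TPM. The skeletal muscle list held 0.169% ± 0.022, nearly all of it Acta1 (1206 ± 233 TPM), Ckm (261 ± 2.6 TPM) and Tnnt3 (55.7 ± 0.3 TPM), whereas the fast myosin genes Myh1 (0.07 ± 0.01 TPM) and Myh4 (2 and 5 counts), the calcium pump Atp2a1 (0.29 ± 0.16 TPM) and Pvalb (0.04 ± 0.01 TPM) were under 1 TPM. All 10 male accessory gland genes (among them Svs2, Svs3a, Svs4, Svs5, Svs6, Pate4, Pbsn, Sbp and Tgm4) and all 7 kidney genes (Umod, Slc12a1, Slc12a3, Slc34a1, Kap, Aqp2 and Lrp2) were under 1 TPM in both libraries. The highest of them were Tgm4 at 0.20 ± 0.10 TPM and Lrp2 at 0.15 ± 0.01 TPM. The lists held 3.17e-05% ± 9.46e-06 and 2.96e-05% ± 1.88e-06. Erythroid genes held 0.039% ± 0.004 (the beta globin Hbb-bs 148 ± 18, the alpha globins Hba-a2 135 ± 18 and Hba-a1 49.8 ± 4.3 TPM, which are near-identical copies and can share reads, and Alas2 0.79 ± 0.27 TPM). Xist, the RNA of the inactive X chromosome, had 81.8 and 94.4 TPM and held 0.0095% ± 0.0011, and the Y-linked genes Eif2s3y (25.6 ± 7.5), Ddx3y (9.58 ± 1.23) and Kdm5d (5.92 ± 1.54 TPM) were detected in both libraries, with a share of 0.0048% ± 0.0013 for the list. The labels describe both sexes in the material.

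**Figure D2:**
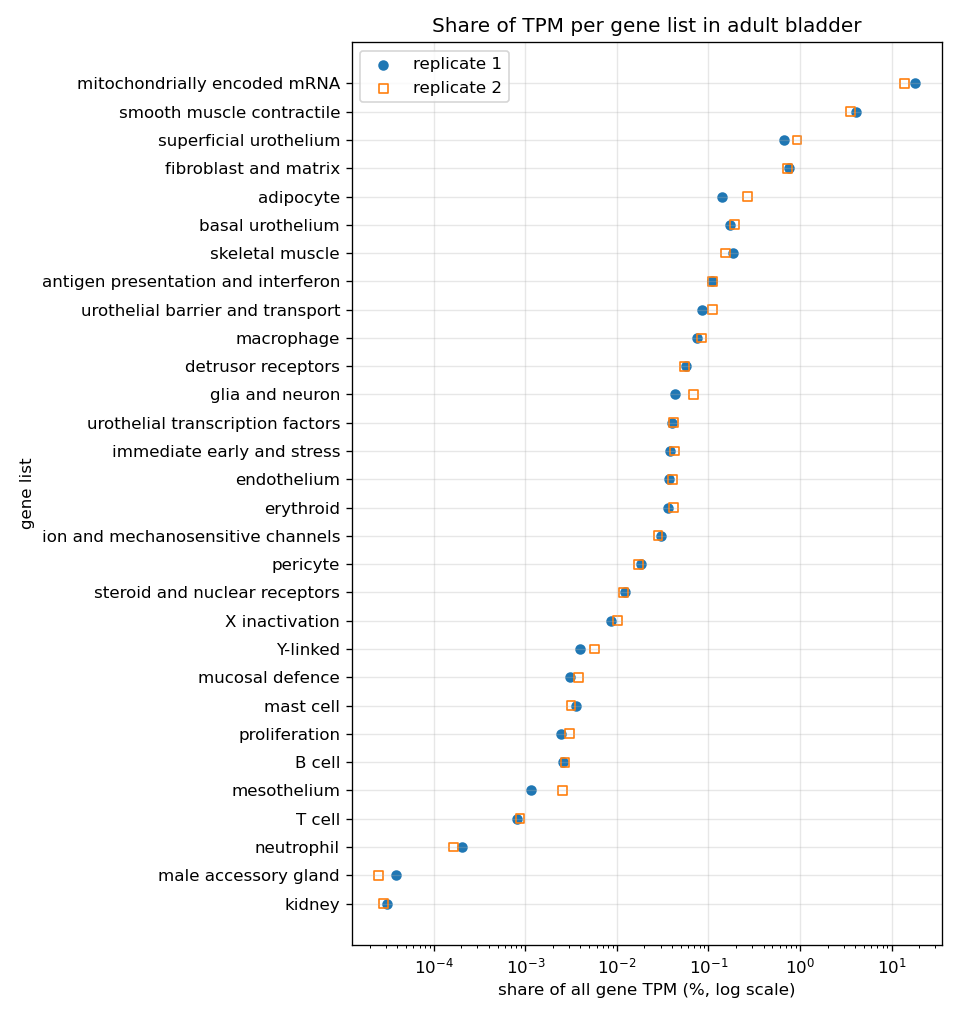
Share of all gene TPM held by each of 30 gene lists (horizontal axis, percent, logarithmic) in replicate 1 (filled circles) and replicate 2 (open squares). Smooth muscle genes hold 4.09% and 3.56%, and the adipocyte list is at 0.141% in replicate 1 and 0.267% in replicate 2.

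Mitochondrially encoded mRNA held 18.1% of TPM in replicate 1 and 14.0% in replicate 2. The short mt-Atp8 transcript took 10.8% and 9.40% of gene TPM with only 0.104% and 0.0540% of the gene counts, and mt-Co1 (11695 ± 3482 TPM) and mt-Co3 (9909 ± 2651 TPM) were next. As a share of gene counts, which are not divided by transcript length, the mitochondrial list held 3.59%.

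Other shares also moved by over 1.5 times between TPM and counts. As a mean share of gene counts, fibroblast genes held 1.67%, urothelial transcription factors 0.0797%, neurotransmitter receptors 0.0934%, channels 0.0802%, steroid receptors 0.0336%, pericyte genes 0.0611%, Xist 0.0610%, Y-linked genes 0.0098%, mesothelial genes 0.0029%, mast cell genes 0.0052%, immediate early genes 0.0620%, kidney genes 0.00021%, neutrophil genes 4.90e-05% and erythroid genes 0.0133%. In the mm9 RPKM values the erythroid list held 0.115%, the immediate early list 0.0902%, Xist 0.0308% and the neutrophil list 9.74e-05%. The neutrophil list held 0.00018% ± 0.00003 of TPM.

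Splice forms were examined in 13 genes, 11 of which had more than 1 quantified transcript, and in 6 of these a single transcript held over 50% of the gene's TPM in both libraries. Tpm2-203, encoding 284 amino acids, held 93.9% ± 1.1 of tropomyosin 2 and Tpm1-215, of the same length, 87.8% ± 0.6 of tropomyosin 1. Smtn-203, encoding 923 residues of smoothelin, held 70.1% ± 1.8, Smtn-201 14.0% ± 1.7 and Smtn-206 13.1% ± 3.2. The alpha-actinin 1 forms Actn1-202 and Actn1-201 held 74.4% ± 0.4 and 25.6% ± 0.4, and Pparg-202 and Pparg-201, encoding 475 and 505 residues, held 69.5% ± 4.8 and 30.5% ± 4.8. For Trp63, the regulator of basal epithelial cells, Trp63-201 held 56.4% ± 7.4 and Trp63-205 35.8% ± 5.3, encoding 586 and 582 residues. Caldesmon was divided among Cald1-210 (34.4% ± 7.6), Cald1-205 (25.9% ± 5.6), Cald1-204 (25.2% ± 9.2) and Cald1-203 (10.4% ± 2.8). Cd44-207, Cd44-203 and Cd44-201 held 46.3% ± 2.8, 23.7% ± 3.5 and 14.6% ± 0.01. The pyruvate kinase forms Pkm-201 and Pkm-202 held 52.9% ± 5.9 and 47.1% ± 5.9, a difference within the spread. In Fn1 the retained-intron transcript Fn1-202 held 38.7% ± 1.2, ahead of Fn1-203 (15.7% ± 4.6), Fn1-214 (14.3% ± 0.5) and Fn1-204 (11.6% ± 1.5), and in Fgfr2 the transcripts Fgfr2-217, Fgfr2-221 and Fgfr2-207 held 35.2% ± 1.1, 21.3% ± 1.6 and 13.6% ± 0.3. Myh11 and Vcl had 1 quantified transcript each, so their splice forms were not analysed here.

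Comparing the libraries with each other shows the spread between these samples, which may be partly technical. The adipocyte and superficial urothelium lists were higher in replicate 2, and the smooth muscle and mitochondrial mRNA lists were higher in replicate 1. All 8 adipocyte genes lay above the median of all genes, with a list median of 0.92 on the log2 scale (replicate 2 over replicate 1, relative to all genes, 100th percentile of 10000 random lists matched on mean expression), and Adipoq, Cidec, Lep and Cfd passed the test between the libraries. A second list of adipocyte genes, chosen later, had a median of 0.14 over its 11 measured members, inside the central 95% of random lists. All 11 superficial urothelium genes lay above it, with a median of 0.40 (percentile 99.99), and none passed at a fold of at least 2. All 15 smooth muscle genes lay below it, with a median of -0.57 (percentile 0.01) and none past the fold, but Tagln, Acta2 and Actg2 had log2 TPM ratios of -0.01, -0.06 and -0.09 against -0.85 for Myh11. Across genes, which are not independent replicates, this ratio had a Spearman correlation of -0.41 with transcript length and -0.02 with GC content, so that longer transcripts tended to be lower in replicate 2. All 13 mitochondrial mRNAs lay below (median -0.84) and 7 passed the test. The medians were 0.69 for 3 mesothelial genes, with Msln past the test, 0.37 for the Y-linked genes, -0.44 for pericyte, -0.28 for steroid receptor, -0.27 for fibroblast and -0.23 for endothelial genes, all outside the central 95% of random lists. Once a trend with GC content and transcript length was removed, a step chosen after the data were seen, the superficial urothelium median moved to 0.24, and the fibroblast and endothelial medians moved to -0.10 and -0.07, inside the central 95%. The median of the second adipocyte list moved to 0.24 (percentile 99.58), outside the central 95%. The steroid receptor median was -0.15 when members under 1 TPM were included.

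**Figure D3:**
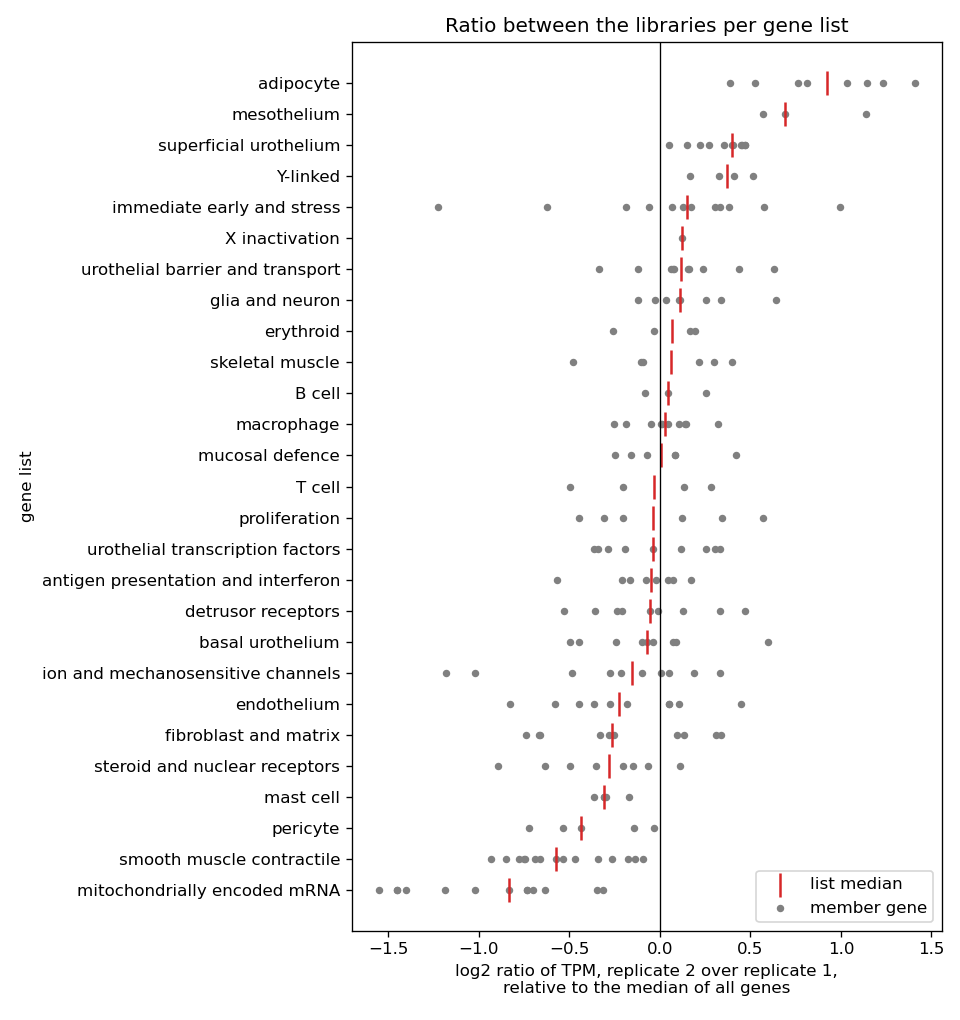
Log2 ratio of TPM between replicate 2 and replicate 1, relative to the median of all genes (horizontal axis), for each member with a mean of at least 1 TPM (grey points) and the list median (red bars). All 8 adipocyte genes lie above 0 and all 15 smooth muscle genes below it.

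Across genes, log2 TPM of the libraries had a Pearson correlation of 0.985 and a Spearman correlation of 0.982 over the 14191 detected genes, which are not independent replicates. The biological coefficient of variation, edgeR's estimate of spread beyond counting error, was 0.182. The test per gene covers counting error only and treats fragments as independent molecules, so its calls describe these libraries and carry no biological error. Of 18003 genes tested, 644 differed at least 2-fold in the exact binomial test with Benjamini-Hochberg adjustment at 0.05, 156 higher in replicate 2 and 488 higher in replicate 1 (11497 with no fold requirement), and 66.2% of genes had an unadjusted p under 0.05, so the files do not hold 1 library deposited more than once. Of the 234 list genes tested 19 were called, and 19 when adjusted over the list alone. Beyond those named, they included Krt14, Cd8a and Atf3, higher in replicate 2, and Cacna1c, Ms4a1 and Egr1, lower. Among genes of at least 5 TPM and 200 counts, the lowest ratios were those of Gm10240 (1675 and 2.83 counts), Gm42418 (-3.80), mt-Rnr2 (-3.34), mt-Rnr1 (-2.79), Lars2 (-2.53), Gm12338 (-2.28), Kcng1 (-1.97), Scarna2 (-1.81), Itprid2 (-1.73) and Nfix (-1.69). The highest were those of Gm10163 (3.16), Hist2h2aa2 (2.34), Gm13370 (2.26), Nnat (1.96), Rgs1 (1.72), Ces1d (1.69), Mid1 (1.51), Gm29008 (1.40), Gm10076 (1.37) and Adipoq (1.32). Some of these ratios differ between TPM, which is adjusted for transcript length, and TMM-normalized counts, which are not. By those counts Ces1d stood at 1.04, Mid1 at 0.90 and Rgs1 at 1.25, and Gm12338 was lower at -3.05. Adipoq moved only to 1.25, so the change was particular to some genes, and its cause was not tested. Gm10240, Gm12338, Gm10163 and Gm13370 are processed pseudogenes, which can share reads with their parent genes.

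The authors' earlier mm9 quantification ranked genes like the mm10 one, with a Spearman correlation of 0.919 across 13682 genes. Upk1a was at 271 RPKM, Acta2 at 1163 RPKM and P2rx1 at 58.6 RPKM in the mean of its replicate values. All 37 mitochondrial genes were listed at 0 in that table, and 20 of the compared genes were listed at 0 there.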

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

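These signals lie in data that the comparisons above do not use, and each exceeds the limit that a count of 0 allows. All of them were singled out after the data were seen, and no explanation was tested for them. Rows for the phiX control genome took 1.32% of the expected counts in replicate 1 and 1.02% in replicate 2. The ERCC spike-in RNAs took 3.69% and 4.96%, with 76 and 84 of 96 species above 0. In the mm9 junction table, 35745 junctions outside the introns of annotated Ensembl transcripts had at least 10 reads, although annotated introns held 96.3% of all junction reads. Among 84068 assembled mm9 models, 27624 overlapped no annotated gene on either strand, and 200 of these had an IDR under 0.1 and a mean of at least 1 RPKM. The highest, at 1120 RPKM on chromosome 1 (mm9, 24621723 to 24681637), was followed by models on chromosome 18 (68851709 to 68852022, 382 RPKM) and chromosome 6 (3150761 to 3151741, 268 RPKM). Chromosome 1 also carries the copies of mitochondrial sequence named above, such as Gm29216 (mm10, 24615706 to 24616197). Positions were not carried over between mm9 and mm10, so whether the highest model covers these copies is open.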

How the results depend on the processing

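The correction for GC content and length was chosen after seeing the data; all other alternatives were planned. Leaving out a library gave 14487 to 14527 detected genes, 3.56 to 4.09% of TPM for smooth muscle, 0.660 to 0.925% for superficial urothelium, 0.173 to 0.193% for basal urothelium, 0.728 to 0.762% for fibroblast and 0.141 to 0.267% for adipocyte genes, -2.23 to -1.17 for the log2 ratio of Chrm2 to Chrm3, 8 gene pairs at least 2-fold apart and 7 genes with a dominant transcript. The mesothelial share was 0.00114% without replicate 2. Without mitochondrially encoded genes smooth muscle held 4.57%, basal urothelium 0.218% and fibroblast genes 0.888%; by CPM they held 5.22%, 0.271% and 1.67%, and by mm9 RPKM 4.51%, 0.269% and 0.824%. Removing genes lowers the denominator by construction, and CPM are not divided by transcript length. All 37 mitochondrial genes stood at 0 in mm9, so its shares lack the mitochondrial part of the denominator as well. The mm9 share of smooth muscle lay close to that without mitochondrial genes. That of basal urothelium lay above and that of fibroblast genes below, and the cause of these remaining mm9 differences was not tested. Without a filter on low values the Pearson and Spearman correlations were 0.995 and 0.967, and by CPM Pearson's was 0.986; the coefficient of variation without a filter was 0.193. The genes differing between the libraries went from 644 to 1166 without a filter, where more genes were tested, and to 11497 with no fold requirement. The mm9 correlation was 0.926 for genes with an IDR under 0.1. Removing the GC and length trend moved the list median of superficial urothelium from 0.40 to 0.24 and of fibroblast genes from -0.27 to -0.10. The log2 ratio of Col1a1 to Col3a1 turned to 0.49 in mm9 RPKM, and the cause was not tested. The list ratios by mm9 RPKM were not run, because those values are not tied to a replicate, and correlations, dispersion and library differences cannot be had from 1 library. No paired analysis was possible because the series holds 1 group. Depth limits the genes at a few counts, such as Slc14a2, Chrm5 and Camp.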

Other observations

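Gene families, chosen after their values were seen, show other features of the tissue. Small proline-rich proteins, components of the barrier of stratified epithelia, held 1.87% ± 0.75 of TPM (n = 2), with 5 of 15 members detected: Sprr2a2, Sprr1a at 1386 ± 23 TPM, Sprr2a3 at 743 ± 241 TPM, Sprr2a1 at 178 ± 56 TPM and Sprr2f at 1.94 ± 0.01 TPM. The Sprr2a copies share reads, so their division is uncertain. Glutathione S-transferases, enzymes of detoxification, held 1.20% ± 0.09, with 23 of 25 detected, led by Gstm1, Gsta4 (1558 ± 294 TPM) and Mgst1 (481 ± 84 TPM). S100 calcium-binding proteins held 0.619% ± 0.198, led by S100a6 (3811 ± 1560 TPM), S100a11 (729 ± 60 TPM) and S100a1 (532 ± 167 TPM), while the neutrophil members S100a8 and S100a9 stayed under 1 TPM. Of 49 keratins 14 were detected, led by Krt19 (637 ± 94 TPM), and of 23 claudins 10. Collagens held 0.520% ± 0.066, and cytosolic ribosomal proteins 11.2% ± 0.6.

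The design names no biological difference between the libraries of its 1 group, so no biological explanation was tested, and the make-up of the tissue pieces is weighed below as a matter of sampling. The tests of RNA without poly(A) tails and of the muscle share were chosen only after the results were seen; the GC and length tests and the second adipocyte list were set down before their results were seen. Differences are log2 ratios of replicate 2 over replicate 1 relative to all genes, and each SD is that of medians of matched random lists.

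Gm42418, mt-Rnr1, mt-Rnr2 and Lars2, picked after the fact from the lowest ratios, were higher in replicate 1, with a median of -3.15 that follows from that choice; mt-Rnr1 and mt-Rnr2 are ribosomal RNA genes, and Lars2 is annotated as protein coding. A trend with GC content and transcript length explained 16.7% of the variance over other genes, and its division between them was not tested. Across genes the ratio had a Spearman correlation of -0.41 with length and -0.02 with GC. Removing the trend left -3.29 (SD 0.18), so the trend as fitted does not account for these ratios. Genes picked for such low ratios could hardly have come back to the level of all genes, so this outcome was close to fixed in advance. Carry-over of RNA without poly(A) tails may contribute, though its test was not made on unseen genes. The 17 small structured RNA and histone cluster genes used include Scarna2 (-1.81) and Hist2h2aa2 (2.34), already named above among the largest ratios. The 17 genes had a median of -0.42 (SD 0.08). That value came from 8 small structured RNAs (-0.79), while 9 histone cluster genes stood at -0.06, so the explanation covers only part of the class. The 13 mitochondrially encoded mRNAs stood at -0.84, so low values were not confined to the small structured RNAs. Incomplete removal of ribosomal RNA stays open, as untested.

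All 8 adipocyte genes were higher in replicate 2, with a median of 0.92. The GC and length trend left 0.81 (SD 0.11) and, as fitted, is not the whole cause. More fat tissue in the replicate 2 sample is a candidate explanation, but its test did not decide: a second list of 12 adipocyte genes, 11 of them measured above the limits, had a median of 0.14 (SD 0.09), under the bound of 2 SD set beforehand. Of the 11 members 9 lay above the median of all genes, with Cd36 and Lpl at 0.60 and 0.61, while Pnpla2, at 93.0 and 80.7 TPM, was at -0.29. After the trend was removed the second list stood at 0.24 (SD 0.08), a value looked at only afterwards, and the explanation stays open.

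Smooth muscle genes were lower and superficial urothelium genes higher in replicate 2, with medians of -0.57 and 0.40. Removing the GC and length trend left -0.52 (SD 0.09) and 0.24 (SD 0.11). Myh11 went from -0.94 to -0.63, Tagln from -0.09 to -0.23 and Mylk from -0.34 to 0.02, the only 1 of 15 muscle genes then above 0. The trend as fitted is therefore not the whole cause of the muscle pattern. It took part of the urothelial difference, and the remainder exceeds 2 SD only narrowly. The correction was tried on a simulated GC trend alone, where a shift of 0 came back as 0.04 and 1 as 1.09. The SD also leaves out error in the fitted trend. A trend with length as the cause of the urothelial pattern therefore stays open. A smaller share of muscle cells alone in the replicate 2 sample should raise all other cell types alike. The superficial median exceeded the mean of the basal urothelium, fibroblast and endothelium medians by 0.59 (SD 0.12). Once the trend was removed the difference was 0.33 (SD 0.12), a value looked at only afterwards. The superficial list thus stood above these other lists, but their medians were known when the test was chosen, so its outcome was fixed. It therefore cannot decide whether a smaller share of muscle cells alone was the whole cause of the higher superficial genes. Fibroblast and endothelial cells can also lie within the muscle layer, so the test cannot decide on a smaller amount of that layer. A smaller muscle share as the cause of the lower muscle genes, and a different amount of superficial epithelium in the samples, stay open, as untested.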
